A study of Homo sapiens with 4 samples.

How the data were processed

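RNA was taken from HCT116 cells after 24 h with HJJ_3_5 or with DMSO, and mRNA libraries were made with a dual-mode Illumina kit, per the labels' protocols. The 4 samples were grouped by their labels into DMSO 1 and 2 and HJJ_3_5 1 and 2. The labels speak of cells with or without the compound and name the control DMSO, which is the name used here.

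The authors deposited a table of raw read counts per gene, 1 column per sample, with no normalization. The counts are whole numbers that sum to a different total in each library, from 29211120 to 36455176. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here. The submitters' processing notes name GRCm38 and mm10, which are mouse builds, while every row of the table is a human Ensembl gene identifier, so the build behind the counts is unknown. The table holds 20263 rows, of which 3401 have no count in any library, and 20148 identifiers were matched to a symbol. Reads shared by overlapping genes, pseudogenes or near-identical copies may have been split or dropped in a way that cannot be seen from the table. Gene positions, transcript length, GC content and 3' UTR length were taken from GENCODE 29 on GRCh38, matched by identifier. Positions are therefore those of that annotation, not of the authors' processing. Length and GC are those of the longest protein-coding transcript of a gene and were known for 99.9% of tested genes.

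From the deposited counts, genes were kept with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 14180. Libraries were scaled by TMM, and HJJ_3_5 was compared with DMSO by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, two-sided, group as the only term, 2 residual degrees of freedom). p-values were adjusted by the Benjamini-Hochberg method, and genes below 0.05 are called higher or lower. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The estimated biological coefficient of variation was 0.193. CPM were computed with TMM-scaled library sizes.

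Before the data were examined, 35 gene lists with 989 distinct genes were fixed, and 6 of these genes were not found in the table. The 32 lists with at least 5 tested genes were tested against the other genes with camera (limma 3.58.1, preset correlation 0.01, two-sided) on voom log2 values, adjusted over lists. None of the 13 calls held with a correlation estimated from the data, where the lowest adjusted p was 0.586. With 2 samples per group such an estimate rests on 2 residual degrees of freedom. The set test then takes its p-value on these as well, so a call was hard to reach whatever the correlation. DNA replication genes had an estimate of -0.0061, below the preset 0.01, and still had a camera adjusted p of 0.586. This setting therefore cannot decide whether correlation between genes made the calls. Counts "adjusted over the list alone" use the same gene p-values, adjusted within the list. Genes were named by a rule fixed at the same time. It takes the 10 largest changes in each direction among called genes whose groups did not overlap, with an average log2 CPM of at least 3. It also takes up to 4 called members with the smallest p from each list, and 13 fixed genes of EMT and proliferation (CDH1, CDH2, VIM, SNAI1, SNAI2, ZEB1, TWIST1, FN1, EPCAM, MYC, CCND1, CDKN1A and MKI67). Genes outside the rule were chosen after their values were seen, and the text says so.

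Alternatives fixed before the data were examined were relative log expression factors, library totals, no filter, at least 10 counts in every library, DESeq2 (1.42.0), limma-voom, a replicate block, an adjusted p below 0.01, an estimated correlation for lists, and leaving out each library. Alternatives added after seeing the data were the removal of a GC and length trend, alone and with the replicate block, and the removal of genes that share exon bases with another protein-coding gene. The trend was fitted in each library with natural splines of 4 degrees of freedom in GC and log length on genes with log2 CPM of at least 3, and entered the model as an offset. The methods were tested on simulated counts for the same 14180 genes and libraries, with 200 genes changed. edgeR recovered 48% of genes changed 2-fold and 92% of genes changed 4-fold, with 1 call among unchanged genes, and made 0 calls of genes and of lists when none was changed. These counts were drawn for each gene independently and without a GC trend. The 0 list calls therefore do not test lists whose genes vary together. The trend removal was run on other simulated counts, to which a GC trend was added (Spearman's rho of fold change with GC 0.712). There 51% and 95% were recovered, with 7 calls among unchanged genes. The fit without trend removal was not scored on those counts, so the recoveries cannot be compared. In all simulated counts, genes of like expression shared a dispersion, taken from its trend with expression in the real fit. Genes that vary more than that dispersion trend were not simulated, and 200 genes were changed where 2473 were called in the data. The recoveries and the calls among unchanged genes therefore need not hold for these libraries. Exact intervals for shares of counts are at the 95% level and cover counting error only, since reads carry no molecular identifiers here. In a comparison of 2 libraries with 2, an exact permutation test cannot go below p = 0.3333. Some single-gene and gene-family results are not reported here.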

Results

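The data were RNA-seq read counts per gene from HCT116 cells, an established human colorectal carcinoma line of epithelial origin. The cells had been cultured for 24 h with HJJ_3_5, which the series title describes as a piperine derivative, or with DMSO, the solvent control. The concentration of HJJ_3_5 is not given in the sources used here. Each of the 2 groups held 2 samples, numbered 1 and 2. Nothing in the labels says whether the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The libraries held 31120459 and 29769568 counts with DMSO and 29211120 and 36455176 with HJJ_3_5. Spearman's rho across genes was 0.986 between the DMSO libraries and 0.980 between the HJJ_3_5 libraries, and the counts of both pairs differed by more than sampling noise.

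The single comparison was HJJ_3_5 against DMSO, which asks how the compound alters gene expression in colon cancer cells, with the epithelial-mesenchymal transition (EMT) named in the series title. Genes of the hypoxia response, glycolysis, mitosis, cytosolic ribosomal proteins and protein folding fell with HJJ_3_5, and genes of DNA replication and NF-kB signalling rose, by a set test with a preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.586 for each). That setting rests on 2 residual degrees of freedom, so it cannot decide whether correlation between genes made the calls. CDH1, which encodes E-cadherin, did not pass the test, and the epithelial and mesenchymal lists as sets did not either in the main fit. Removal of a GC and length trend was added after seeing the data. With it the epithelial set was called lower (camera adjusted p = 0.0166, and adjusted p = 0.479 with an estimated correlation). The mesenchymal set was not called with it (camera adjusted p = 0.17). Of 14180 genes tested, 1300 were higher and 1173 lower with HJJ_3_5 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), which is 17.4% of the genes tested. Of these, 456 were at least 2-fold higher and 587 at least 2-fold lower. Both HJJ_3_5 libraries lay on the same side of both DMSO libraries for 69.0% of the genes, where chance gives 33.3% for a gene. Genes of a library are not independent, so this share cannot tell an effect of HJJ_3_5 from other differences between the libraries.

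The count of called genes fell without DMSO 1, DMSO 2 or HJJ_3_5 1, but not without HJJ_3_5 2. edgeR called 12 genes higher and 40 lower without DMSO 1, 0 higher and 4 lower without DMSO 2, 0 and 0 without HJJ_3_5 1, and 976 higher and 1716 lower without HJJ_3_5 2. At an unadjusted p below 0.05 the counts without HJJ_3_5 1 were 2054 higher and 2249 lower, and those without DMSO 2 were 1628 and 1664. Of the 140 genes taken by the naming rule, 132 were called with all libraries. A fit without a library leaves 1 sample in a group and fewer degrees of freedom. A call lost there can reflect this as well as the library left out. The lowest adjusted p was 0.0244, so edgeR called 0 genes at an adjusted p below 0.01, where DESeq2 called 2638 and limma-voom 0; 5578 genes had an unadjusted p below 0.05. Scaled by library totals in place of TMM (trimmed mean of M-values) factors, which moved all log2 fold changes by 0.187, 2614 genes were higher and 818 lower (76.2% higher, against 52.6%). Fold changes below are relative to TMM scaling, ± values after them are standard errors, and levels are CPM (counts scaled to a common library size with TMM) as mean ± SD (n = 2).

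Libraries also differed by transcript composition. Fold changes rose with the GC content of the transcript, with a median log2 fold change of -0.24 in the fifth of genes with the lowest GC and 0.22 in the fifth with the highest. In the fifth of genes with the longest transcripts the median was -0.33, against 0.09 in the shortest. Differences between libraries of the same group, library 2 minus library 1, followed GC as well. Spearman's rho across genes was -0.418 with DMSO and -0.611 with HJJ_3_5, against 0.379 between groups. The sign within a group depends on the order of subtraction, and the value between groups rests on 2 libraries per group. With this trend removed per library, 1120 of the 1300 higher genes and 909 of the 1173 lower genes were still called in the same direction.

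**Figure D1:**
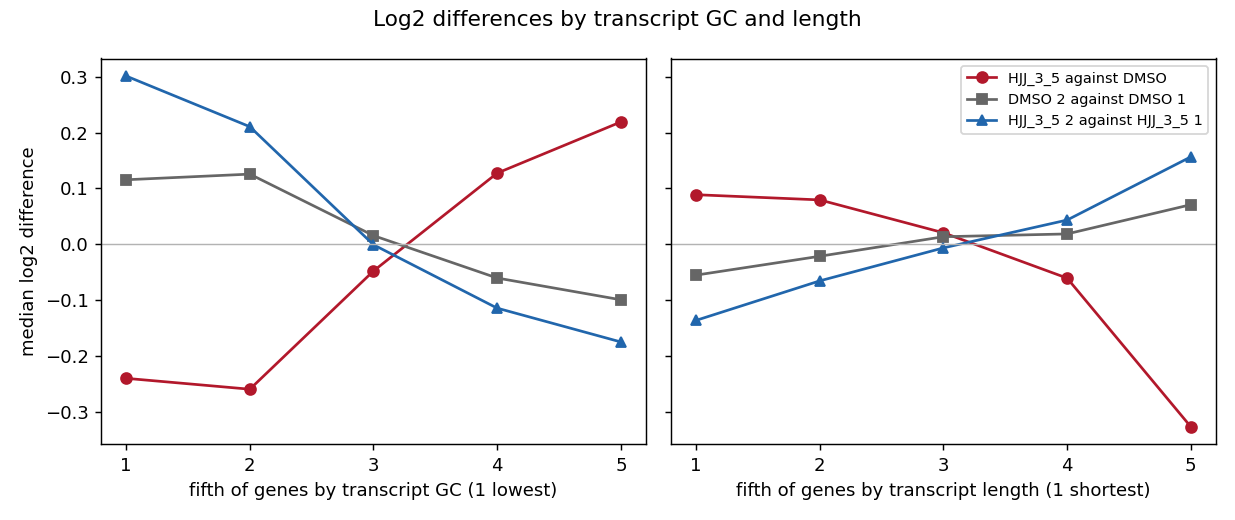
Median log2 difference (vertical axis) of genes in 5 equal groups by transcript GC content (left) or transcript length (right). Red circles compare HJJ_3_5 with DMSO, grey squares DMSO 2 with DMSO 1 and blue triangles HJJ_3_5 2 with HJJ_3_5 1. The red line climbs from -0.24 to 0.22 with GC and ends at -0.33 among the longest transcripts.

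The largest decrease among well-expressed genes was in ARRDC4, an arrestin-domain gene induced by glucose through MondoA and ChREBP (ENSG00000140450, GRCh38 chromosome 15, 97960698 to 97973838). It went from 400.3 ± 14.4 CPM with DMSO to 32.2 ± 4.0 CPM with HJJ_3_5, a log2 fold change of -3.64 ± 0.13 (adjusted p = 0.0244). The HIF1 target ANKRD37 (-3.18), the kinetochore gene CENPF (-3.10), the cadherin FAT4 (-2.88), the centrosomal gene ALMS1 (-2.80), the chromatin regulator ARID5B (-2.64) and the TNF-family ligand EDA (-2.58) came next. The collagen prolyl hydroxylase P4HA1 (-2.58), the histone demethylase KDM3A (-2.56) and MKI67, the proliferation marker Ki-67 (-2.55), completed the 10. With the GC and length trend removed, the log2 fold changes were smaller for CENPF (-2.38), FAT4 (-2.04), ALMS1 (-2.02) and MKI67 (-1.96), and all 4 were still called. CENPF and ALMS1 differed widely between the DMSO libraries, with SDs of 83.4 and 9.55 CPM around means of 119 and 18.1 CPM. Among increases, SLC16A6, a monocarboxylate transporter family gene (ENSG00000108932, chromosome 17, 68267026 to 68291267), went from 6.37 ± 0.20 to 43.5 ± 5.0 CPM, a log2 fold change of 2.77 ± 0.15 (adjusted p = 0.0244). NTSR1, the neurotensin receptor (ENSG00000101188, chromosome 20, 62708837 to 62762771), went from 178 ± 10 to 750 ± 35 CPM (2.08 ± 0.10, adjusted p = 0.0244). The rest of the 10 were the transcription factor ATF5 (2.41), the iron regulator HFE (2.10), the hyaluronan synthase HAS3 (2.10), the importin IPO4 (2.09), the galactosyltransferase B3GALT6 (2.09), KRCC1 (2.02), the Golgi transport gene GOLT1B (2.01) and ZBTB9 (2.00). GOLT1B differed widely between the DMSO libraries too, at 13.04 ± 6.71 CPM, so the size of its rise depends on which of them is used. IPO4 and ZBTB9 share exon bases with another gene on their strand, and SLC16A6, ATF5, HAS3 and ANKRD37 with a gene on the other strand, so their reads could be split between genes, the strand setting of the counting not being given. The same holds for PGK1, RRS1, DNAJB4, AHRR, OSGIN1 and MT-ND4 on their own strand, and for FAM162A, KIF20A, ANLN, CHAF1A, MCM2, MYBBP1A, MRTO4, DNAJB1, TCF7, KRT18, CYP1B1 and CCND1 with the other strand, all named below.

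**Figure D2:**
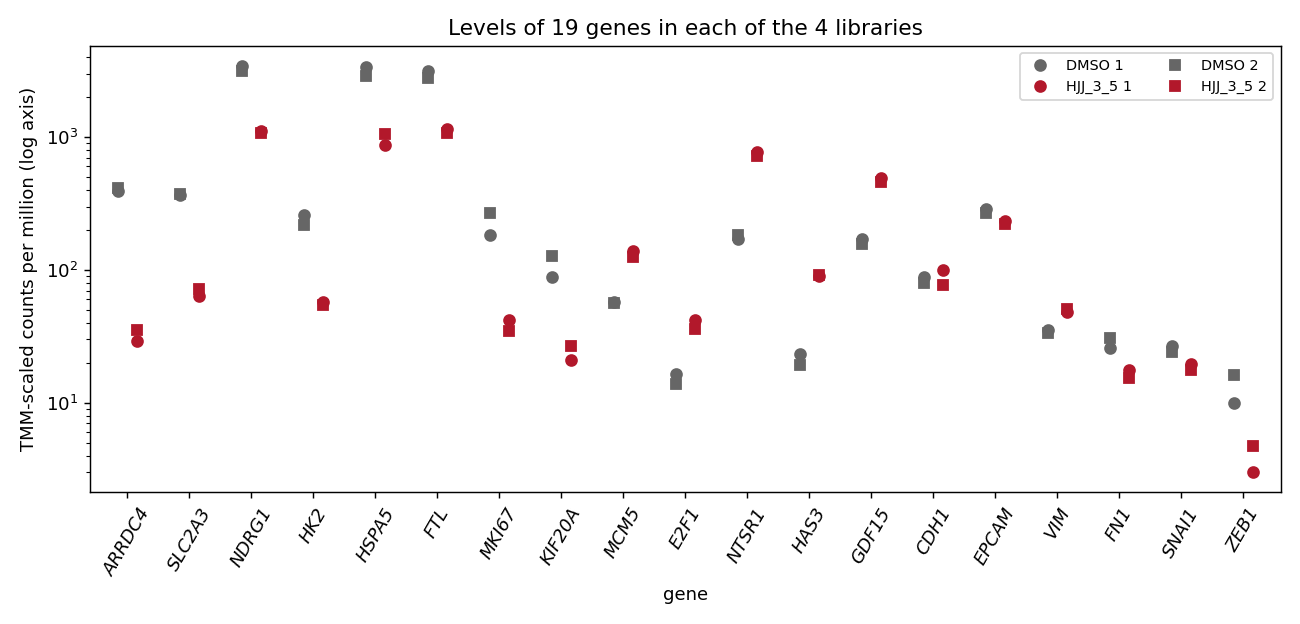
TMM-scaled CPM on a log axis for 19 genes, 1 point per library (grey DMSO, red HJJ_3_5; circles library 1, squares library 2). NDRG1 fell from a mean of 3267 to 1087 CPM, NTSR1 rose from 178 to 750 CPM, and the CDH1 points of the groups overlap.

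Hypoxia-inducible genes fell as a group. Of 27 tested, 18 were lower and 0 higher (19 lower, adjusted over the list alone), all 27 fold changes were negative, and the median log2 fold change was -1.16 (camera adjusted p = 2.31e-11, and adjusted p = 0.586 with an estimated correlation). SLC2A3, the glucose transporter GLUT3, went from 371 ± 6 to 67.5 ± 5.4 CPM (-2.46 ± 0.11, adjusted p = 0.0244). NDRG1, a stress-responsive gene, fell from 3267 ± 201 to 1087 ± 21 CPM (-1.59 ± 0.10, adjusted p = 0.0244), and FAM162A, a HIF1 target, fell by 1.37. Glycolytic enzymes fell too, with 11 of 20 lower and 0 higher (11 lower, adjusted over the list alone) and a median of -0.47 (camera adjusted p = 0.000142, and adjusted p = 0.586 with an estimated correlation). Hexokinase HK2, at the first step of the pathway (ENSG00000159399, chromosome 2, 74833981 to 74893359), went from 239 ± 30 to 55.7 ± 2.3 CPM (-2.10 ± 0.13, adjusted p = 0.0244). The aldolase ALDOC and the enolase ENO2 fell by 1.49 and 1.16. The phosphoglycerate kinase PGK1 fell by 0.83, but its call was lost with the GC and length trend removed (-0.48, adjusted p = 0.0833). With the trend removed, the list medians were -0.91 for hypoxia and -0.56 for glycolysis. With library totals 6 glycolytic genes were lower and 1 higher, with a median of -0.28.

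Mitotic genes fell and genes of DNA replication rose. Of 50 G2/M and mitosis genes, 15 were lower and 1 higher (29 and 1, adjusted over the list alone), with a median of -0.92 (camera adjusted p = 6.91e-08, and adjusted p = 0.586 with an estimated correlation). MKI67 went from 226 ± 60 to 38.5 ± 5.2 CPM (-2.55 ± 0.23, adjusted p = 0.0253), the kinesin KIF20A from 108 ± 27 to 23.9 ± 3.9 CPM (-2.17 ± 0.24, adjusted p = 0.0273), and the cytokinesis genes ANLN and ECT2 fell by 2.23 and 1.73. The 1 higher gene was FOXM1, a transcription factor of mitotic genes (0.59). In the 35 genes of the list left without those that overlap another gene, 0 were higher and 12 lower, with a median of -0.74. The median of the list was -0.63 without HJJ_3_5 1 and -1.17 without HJJ_3_5 2. The transcripts of this list had a median GC content of 42.6%, the replicate libraries differed in it by medians of 0.32 with DMSO and 0.37 with HJJ_3_5, and its median was -0.70 with the trend removed. Of 45 DNA replication and G1/S genes, 13 were higher and 2 lower (24 and 4, adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.00057, and adjusted p = 0.586 with an estimated correlation). The helicase subunit MCM5 went from 56.6 ± 1.0 to 132 ± 10 CPM (1.22 ± 0.11, adjusted p = 0.0244), E2F1, a G1/S transcription factor, rose by 1.36 ± 0.16 (adjusted p = 0.0273), and the chromatin assembly subunit CHAF1A and MCM2 rose by 1.17 and 0.93. The 2 lower genes were RRM2 (-0.59) and ORC1 (-0.67). With library totals 27 of this list were higher and 1 lower. Among 18 replication-dependent histone genes, 5 were lower and 0 higher (6 lower, adjusted over the list alone), and the set did not pass the test (camera adjusted p = 0.0614), although it did without DMSO 2 (0.0197), with library totals (0.0201) and without genes that overlap another gene (0.0295). The 5 were H2BC4 (-2.98), H2BC21 (-1.96), H2BC11 (-1.60), H1-2 (-1.42) and H2BC5 (-1.01). Levels were low for H2BC4 and H2BC21, at 0.90 and 1.73 CPM with HJJ_3_5, and 18 of the 43 listed genes in the table passed the filter. Histone genes are near-identical copies, so their counts are uncertain. FOXM1, RRM2, ORC1 and H2BC11 were named after their values were seen.

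Cytosolic ribosomal protein genes fell, with 16 of 56 lower and 0 higher (21 lower, adjusted over the list alone) and a median of -0.31 (camera adjusted p = 6.91e-08, and adjusted p = 0.586 with an estimated correlation). RPLP0 went from 2454 ± 5 to 1675 ± 27 CPM (-0.55 ± 0.08, adjusted p = 0.0295), RPS4X fell by 1.29 ± 0.22 (adjusted p = 0.0345) and RPL11 by 0.60. The set was called with library totals and without HJJ_3_5 2 too, but its median became -0.12, with 2 genes lower, and -0.20, with 8 lower. RPL11 lost its call with library totals, and ribosomal proteins have many processed pseudogenes that can take reads. Nucleolar and ribosome biogenesis genes rose, with 12 of 40 higher and 0 lower (16 and 1, adjusted over the list alone) and a median of 0.25 (camera adjusted p = 0.0092, and adjusted p = 0.586 with an estimated correlation). MYBBP1A, a nucleolar protein, went from 29.7 ± 2.2 to 77.3 ± 3.7 CPM (1.38 ± 0.12, adjusted p = 0.0244), POLR1A, the catalytic subunit of RNA polymerase I, rose by 1.15 ± 0.11 (adjusted p = 0.0271), and the ribosome assembly factors RRS1 and MRTO4 rose by 1.65 and 1.26. The set's call was lost without HJJ_3_5 2 (adjusted p = 0.0914) and without genes that overlap another gene (0.535), among which are RRS1, MYBBP1A and MRTO4. In the 24 genes then left the median turned to -0.03, with 5 higher and 0 lower, while with library totals the median of the 40 was 0.44, with 18 higher.

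Genes of protein folding fell. Of 29 endoplasmic reticulum (ER) chaperone and unfolded protein response genes, 9 were lower and 0 higher (10 and 1, adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0022, and adjusted p = 0.586 with an estimated correlation). HSPA5, the ER chaperone BiP (ENSG00000044574, chromosome 9, 125234853 to 125241330), went from 3106 ± 353 to 968 ± 131 CPM (-1.68 ± 0.15, adjusted p = 0.0244). HERPUD1, of ER-associated degradation, fell by 1.47 ± 0.17 (adjusted p = 0.0273) and SEC24D, a COPII coat subunit, by 1.06. Of 27 heat shock response genes, 5 were lower and 0 higher (15 and 2, adjusted over the list alone), with a median of -0.39 (camera adjusted p = 0.00555, and adjusted p = 0.586 with an estimated correlation). These were HSPA8 (-1.65), HSP90AB1 (-1.32), DNAJB1 (-0.94), DNAJB4 (-0.83) and HSPA1A (-0.46), the last named after its value was seen. HSPA8, HSP90AB1 and HSPA1A have near-identical copies. With library totals, 5 ER genes were lower and 1 higher (median -0.17), and 4 heat shock genes lower and 3 higher (median -0.21). With the GC and length trend removed these were 8 and 2, and 10 and 2. Among 37 genes of the ATF4 and integrated stress response, 12 were higher and 5 lower (17 and 7, adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0477, and adjusted p = 0.586 with an estimated correlation). TRIB3, a pseudokinase, went from 63.3 ± 5.9 to 191 ± 12 CPM (1.59 ± 0.12, adjusted p = 0.0244), the stress cytokine GDF15 from 164 ± 9 to 474 ± 24 CPM (1.53 ± 0.10, adjusted p = 0.0244), and PSAT1, of serine synthesis, rose by 1.22. The 5 lower genes, named after their values were seen, were DDIT3, which encodes CHOP (-1.82), DDIT4 (-1.34), the transfer RNA synthetases GARS1 (-0.93) and SARS1 (-0.67), and SLC7A5 (-0.68). This set's call was lost without DMSO 2 (adjusted p = 0.157), without HJJ_3_5 2 (0.118), with library totals (0.12), with the GC and length trend removed (0.109), with no filter on low counts (0.0517), with 10 counts in every library (0.0627) and without overlapping genes (0.137). Its median was 0.16 without DMSO 2 and 0.43 with library totals.

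Of 24 NF-kB and cytokine genes, 10 were higher and 0 lower (11 higher, adjusted over the list alone), with a median of 0.57 (camera adjusted p = 0.00219, and adjusted p = 0.586 with an estimated correlation). CXCL8, the chemokine interleukin 8, went from 11.2 ± 1.0 to 29.2 ± 5.9 CPM (1.37 ± 0.20, adjusted p = 0.0293). The chemokine CXCL2 rose from 0.95 ± 0.09 to 3.87 ± 0.60 CPM (2.03 ± 0.26, adjusted p = 0.0273), the growth factor CSF1 by 1.02, and LIF from 197 ± 3 to 284 ± 6 CPM (0.53 ± 0.09, adjusted p = 0.0317). Of 26 immediate early and AP-1 genes, 7 were lower and 3 higher (11 and 4, adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.0472, and adjusted p = 0.697 with an estimated correlation). The transcription factor EGR1 went from 649 ± 64 to 273 ± 36 CPM (-1.25 ± 0.14, adjusted p = 0.0273), and ZFP36, which promotes mRNA decay, KLF10 and MCL1, an anti-apoptotic BCL2 relative, fell by 1.69, 0.97 and 0.81. The 3 higher genes, named after their values were seen, were EGR3 (1.31), NR4A2 (0.73) and JUND (0.65). The call on this set was lost without DMSO 1 (adjusted p = 0.341), where its median was -0.09, without HJJ_3_5 2 (0.285), with 10 counts in every library (0.0605) and without overlapping genes (0.137). With library totals its median was -0.13. Of 19 WNT targets, 5 were higher and 1 lower (8 and 1, adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0464, and adjusted p = 0.586 with an estimated correlation), and the call was lost without DMSO 2 (0.127), without HJJ_3_5 1 (0.111), with 10 counts in every library (0.0625) and without overlapping genes (0.137). With library totals 8 were higher and 0 lower, with a median of 0.51. The higher genes were MMP7 (1.89, named after its value was seen), SP5 (0.98), the transcription factor TCF7 (0.76), the WNT antagonist DKK1 (0.52) and the receptor EPHB2 (0.47), and the lower gene was NKD1, a WNT feedback inhibitor (-0.64). With the GC and length trend removed, the calls on NKD1 (-0.04, adjusted p = 0.798) and SP5 (0.66; 0.0833) were lost.

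**Figure D3:**
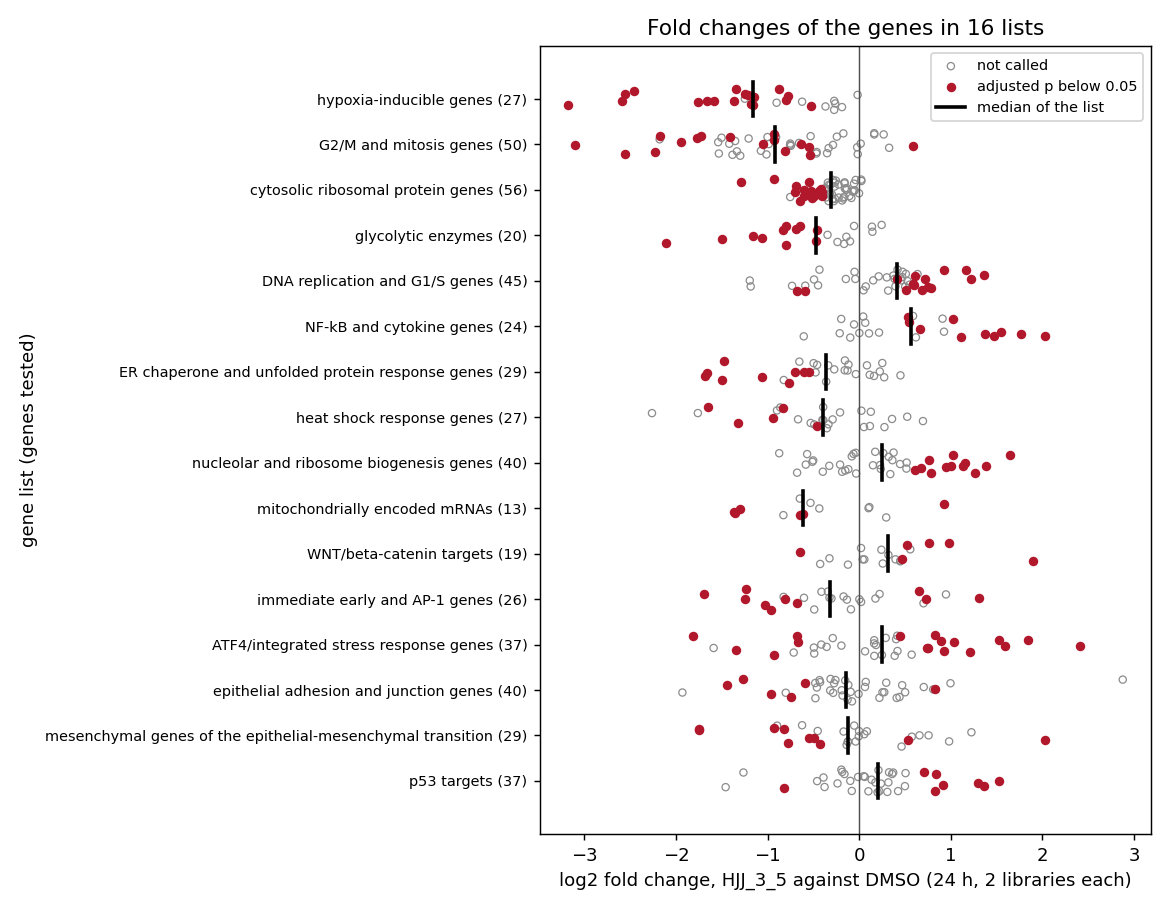
Log2 fold change (horizontal axis) of each tested gene in 16 lists, HJJ_3_5 against DMSO, with called genes filled red, other genes open and the list median as a black bar. The 27 hypoxia-inducible genes all lie below 0 with a median of -1.16, while the epithelial and mesenchymal lists hold genes on both sides; the epithelial and mesenchymal medians change sign when libraries are scaled by their totals.

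For EMT, members went in both directions. CDH1 was at 84.5 ± 6.2 CPM with DMSO and 88.3 ± 16.1 CPM with HJJ_3_5 (0.06 ± 0.16, adjusted p = 0.798), and EPCAM, an epithelial surface protein, at 277 ± 12 and 228 ± 9 CPM (-0.28 ± 0.09, adjusted p = 0.0948). ZEB1, a transcription factor that represses CDH1 (ENSG00000148516, chromosome 10, 31318495 to 31529814), fell from 13.1 ± 4.4 to 3.88 ± 1.19 CPM (-1.74 ± 0.35, adjusted p = 0.0407). Fibronectin, FN1, fell from 28.3 ± 3.8 to 16.5 ± 1.6 CPM (-0.78 ± 0.16, adjusted p = 0.0418), and vimentin, VIM, rose from 34.4 ± 1.0 to 49.6 ± 1.9 CPM (0.53 ± 0.11, adjusted p = 0.044). With the GC and length trend removed, the adjusted p was 0.0874 for FN1 and 0.0816 for VIM. The EMT transcription factors SNAI1 (-0.45, adjusted p = 0.079), SNAI2 (0.57; 0.186) and TWIST1 (-0.04; 0.894) did not pass, and SNAI1 did with the trend removed (-0.69; 0.0195). CDH2, which encodes N-cadherin, had 0, 4, 0 and 5 counts and was not tested. Of 29 mesenchymal genes tested, 8 were lower and 2 higher (8 and 2, adjusted over the list alone, camera adjusted p = 0.294). The 2 higher genes were VIM and SPARC, a matrix glycoprotein (2.03 ± 0.26; 5.01 ± 0.36 CPM with HJJ_3_5), and the lower ones included the collagen COL1A1, from 65.7 ± 1.4 to 37.1 ± 3.9 CPM. The mesenchymal list had 6 lower and 1 higher with the GC and length trend removed. Of 40 epithelial adhesion and junction genes, 5 were lower and 1 higher (5 and 1, adjusted over the list alone, camera adjusted p = 0.251). With library totals 4 were lower and 5 higher, against 4 lower and 3 higher in the mesenchymal list. Keratin KRT18 rose by 0.83 ± 0.12 (adjusted p = 0.0293), while the splicing factor ESRP1 (-0.96), the desmosomal DSP (-1.27), the junction proteins CGN (-0.74) and TJP1 (-1.45), and the transcription factor ELF3 (-0.60) fell, TJP1 and ELF3 being named after their values were seen. With the GC and length trend removed, the epithelial set was called lower, with 14 genes lower and 3 higher and a median of -0.27 (camera adjusted p = 0.0166, and adjusted p = 0.479 with an estimated correlation). In the TGF-beta and SMAD list, 2 of 29 genes were higher and 3 lower (2 and 3, adjusted over the list alone, camera adjusted p = 0.262), and 4 and 5 with the trend removed.

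Mitochondrially encoded mRNAs took 6.59% (95% exact binomial interval 6.581 to 6.599) and 7.73% (7.716 to 7.736) of counts with DMSO, and 5.56% (5.555 to 5.572) and 5.34% (5.333 to 5.347) with HJJ_3_5; these intervals cover counting error only. Of 13 tested, 5 were lower and 1 higher (9 and 1, adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.0254, and adjusted p = 0.655 with an estimated correlation). MT-ND4 fell by 1.30 ± 0.17 (adjusted p = 0.0275) and MT-ND1 rose by 0.92 ± 0.14 (adjusted p = 0.0297), both subunits of respiratory complex I. The call on the set was lost without DMSO 2 (adjusted p = 0.0557), without HJJ_3_5 2 (0.0914), with the GC and length trend removed (0.268, median -0.27) and without genes that overlap another gene (0.625). In the 8 genes then left the median was -0.15, with 1 higher and 1 lower.

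Other lists did not pass the set test, though single members did. Of 37 p53 targets, 7 were higher and 1 lower (7 and 1, adjusted over the list alone, camera adjusted p = 0.142). Their median log2 fold change was 0.20, which became 0.11 without HJJ_3_5 2 and 0.22 without DMSO 1. The pro-apoptotic BBC3 (PUMA) went from 23.0 ± 1.9 to 59.3 ± 5.2 CPM (1.37 ± 0.14, adjusted p = 0.0273), while CDKN1A, the p53 target p21, was at 275 ± 43 and 246 ± 20 CPM (-0.16 ± 0.15, adjusted p = 0.458). All 4 called members of the 17 genes of AHR and xenobiotic metabolism were higher (4 and 0, adjusted over the list alone, camera adjusted p = 0.251): ALDH3A1 (1.40), CYP1B1 (1.31), the AHR repressor AHRR (1.30) and CYP1A1, from 5.07 ± 0.26 to 12.2 ± 0.4 CPM (1.27 ± 0.16, adjusted p = 0.0273). Of 25 cholesterol genes, 6 were higher and 2 lower (7 and 3, adjusted over the list alone, camera adjusted p = 0.194). Fatty acid synthase FASN went from 3118 ± 359 to 5061 ± 537 CPM (0.70 ± 0.14, adjusted p = 0.0391), in a list with 4 of 19 higher and 1 lower (7 and 2, adjusted over the list alone, camera adjusted p = 0.46). Of 33 NRF2 antioxidant genes, 6 were higher and 2 lower (8 and 2, adjusted over the list alone, camera adjusted p = 0.251), the lower ones being the ferritin light chain FTL, from 2937 ± 253 to 1115 ± 58 CPM (-1.40 ± 0.11, adjusted p = 0.0244), which has processed pseudogenes, and OSGIN1 (-0.84). CCND1, cyclin D1, was at 466 ± 15 and 581 ± 38 CPM (0.32 ± 0.09, adjusted p = 0.0784, and 0.0473 with the trend removed). MYC was at 16.6 ± 2.9 and 13.3 ± 12.8 CPM (-0.32 ± 0.76, adjusted p = 0.783), so its HJJ_3_5 libraries differed by more than the groups did. With library totals there were 11 higher and 1 lower of the p53 targets, 12 and 2 of the cholesterol genes, 8 and 0 of the fatty acid list and 12 and 2 of the NRF2 genes, which had 8 and 4 with the trend removed.

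The remaining lists did not pass the set test either. Members passing the test were 5 higher and 2 lower of 33 apoptosis genes (5 and 2, adjusted over the list alone, camera adjusted p = 0.155), and 6 lower and 0 higher of 40 autophagy and lysosome genes (6 and 0; 0.0614). The autophagy set was called lower without HJJ_3_5 1 (adjusted p = 0.0198), with no filter on low counts (0.0442) and with the trend removed (0.0248), while its median of -0.13 became 0.06 with library totals, -0.21 without HJJ_3_5 1 and -0.08 without HJJ_3_5 2. There were 4 lower and 1 higher of 22 ERK pathway genes (5 and 3; 0.671), among them AREG, an EGFR ligand, which fell from 771 ± 25 to 375 ± 6 CPM (-1.04 ± 0.09, adjusted p = 0.0244). Colonocyte differentiation had 2 higher and 1 lower of 10 (2 and 1; 0.46), stem cell and plasticity markers 1 higher and 2 lower of 10 (1 and 2; 0.916), and YAP targets 2 higher and 1 lower of 19 (2 and 1; 0.387). Nuclear-encoded respiratory chain genes had 2 lower of 40 (0, adjusted over the list alone; 0.461), tubulins 2 lower of 16 (1; 0.565), and interferon-stimulated genes 1 higher and 1 lower of 31 (1 and 1; 0.671). With library totals there were 8 higher and 1 lower of the apoptosis genes, 3 and 4 of the autophagy genes, 5 and 4 of the ERK pathway genes, 3 and 0 of the colonocyte genes, 1 and 0 of the respiratory chain genes, 0 and 1 of the tubulins and 5 and 1 of the interferon-stimulated genes. With the GC and length trend removed there were 8 higher and 3 lower of the apoptosis genes, 3 and 5 of the ERK pathway genes, 4 and 1 of the colonocyte genes, 4 and 3 of the respiratory chain genes, 1 and 4 of the tubulins and 6 and 3 of the interferon-stimulated genes, with none of these sets called.

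Several markers of cell types other than epithelium had no counts, while others on the same lists were counted. CD68, a leukocyte marker, had 1256, 1019, 841 and 775 counts, in the order DMSO 1, DMSO 2, HJJ_3_5 1, HJJ_3_5 2. The endothelial marker ESAM had 365, 312, 310 and 361, and the neuroendocrine marker SCG2 356, 445, 310 and 717. PTPRC, a leukocyte marker, and DCN and LUM, of fibroblasts, had 0 counts in all 4 libraries, which allows up to 0.103 CPM of the total in the shallowest library (3 counts), if their reads were assigned to them. Of 16 leukocyte markers 6 were tested and 1 was higher (2 higher and 1 lower, adjusted over the list alone, camera adjusted p = 0.669), LYZ, at 4, 5, 33 and 33 counts. Fibroblast, endothelial and neuroendocrine markers had 4, 3 and 4 genes tested, too few for the set test, and the 1 called gene among them was COL1A1, also in the mesenchymal list. Of the fibroblast markers, COL6A1 was the most abundant, with 9089 and 8302 counts with DMSO and 10101 and 12205 with HJJ_3_5, a collagen that epithelial lines can also express.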

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

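Trend removal, its combination with the replicate block, and the removal of overlapping genes were chosen after seeing the data. No named gene changed the sign of a called fold change in any setting that kept all libraries. Among all called genes, 20 of the lower and 0 of the higher changed sign with the GC and length trend removed. Against 1300 genes higher, 1173 lower and 1043 changed at least 2-fold, library totals gave 2614 higher, DESeq2 gave 2161 lower (275 genes had no adjusted p), and an adjusted p below 0.01 gave 0 for all of these with edgeR, the lowest adjusted p being 0.0244. Leaving out each library gave 0 to 976 higher, 0 to 1716 lower and 0 to 1548 changed at least 2-fold. The lone sample of a group is then assumed to vary like the other group, with fewer degrees of freedom. At an unadjusted p below 0.05 those fits still had 1628 to 2565 genes higher and 1664 to 3226 lower. Against 5 lists higher and 8 lower, an estimated correlation gave 0 and 0 (2 lists had an unadjusted p below 0.05), 10 counts in every library gave 3 higher, leaving out libraries gave 3 to 6 higher and 6 to 9 lower, and removing overlapping genes gave 2 higher. The hypoxia, G2/M, ribosomal protein, glycolysis, DNA replication, NF-kB, ER chaperone and heat shock lists were called in each setting run for lists (DESeq2 and limma-voom were run for genes only) but the estimated correlation. With 10 counts in every library the adjusted p was 0.0605 for AP-1, 0.0625 for WNT targets and 0.0627 for the ATF4 list, and without overlapping genes it was 0.137 for each of these. Of the 140 named genes, 14 lost and 2 gained a call with the trend removed, 11 lost and 1 gained with library totals, and 16 (without HJJ_3_5 2) to 132 (without HJJ_3_5 1) lost it without a library. For other changed values the cause was not tested.

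The replicate numbers are shared by the labels only. Deviations of same-numbered libraries from their group means correlated at r = 0.167 across genes, with 2 pairs. With a replicate block 2077 genes were higher and 2540 lower, with 3 lists higher and 6 lower (not called were WNT targets and mitochondrially encoded mRNAs, adjusted p = 0.0555 each, and the ATF4 and AP-1 lists, 0.0735 each), and with the block and the trend removed 2584 were higher and 2397 lower. Depth limits the test at low counts, where genes such as CDH2 were not tested.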

Other observations

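The tests of the GC trend, of the trend in the hypoxia and glycolysis lists, of gaps in both groups, of overlap and of 3' UTR length, and the gene families, were chosen after the results were seen. Among 44 families defined by symbol prefix, mitochondrial ribosomal protein genes rose, with 15 of 78 called higher and 1 lower and a median log2 fold change of 0.23 (camera adjusted p = 0.00501 over the families, 0.0138 with the GC and length trend removed, and adjusted p = 0.708 with an estimated correlation). MRPL12 went from 83.4 ± 2.3 to 162.8 ± 17.9 CPM (0.97 ± 0.12, edgeR adjusted p = 0.0273), while MRPL17 fell by 0.53. Of 36 genes of histone lysine methylation and demethylation (symbols starting with KMT, SETD or KDM), 11 were lower and 1 higher, with an adjusted p of 0.027 that became 0.146 with the trend removed (0.708 with an estimated correlation). The medians of these families kept their sign under each scaling run, at 0.41 and -0.25 with library totals against 0.23 and -0.44.

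Fold changes rose with transcript GC. Libraries of the same group differed along GC too. Spearman's rho, library 2 minus library 1, was -0.611 with HJJ_3_5, and its absolute value was 0.4182 with DMSO. GC bias of single libraries is therefore a candidate source of the trend. As the cause of most calls it is argued against, since 82.05% of called genes were called in the same direction once the trend was removed. The log2 slope per 10 points of GC was -0.07 and -0.19 with DMSO and 0.24 and 0.01 with HJJ_3_5, and an exact permutation test of the slopes gave p = 0.3333, the smallest that 2 libraries against 2 allow. A treatment response that follows GC therefore cannot be told apart from library preparation.

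Hypoxia-inducible and glycolytic genes fell together. The GC and length trend is argued against as the cause, since the medians with it removed were -0.9123 for the hypoxia list and -0.5611 for the glycolysis list, both still called by camera with the preset correlation, though not with an estimated one (adjusted p = 0.479 for each). A single library is argued against as well, by a test set before its result was seen, since the hypoxia median nearest 0 over the 4 leave-outs was -1.0112. Oxygen, cell density or glucose that differed between dishes stays open. The DMSO libraries differed in the hypoxia list by a median of -0.0719, but no dish condition is recorded, so this cannot be told apart from an effect of HJJ_3_5, which is a hypothesis here.

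Single genes differed several fold between replicates. Of 10661 genes with log2 CPM of at least 3, 131 differed by over 1.5 on the log2 scale between the libraries of a group after the trend was removed (73 with DMSO, 80 with HJJ_3_5 and 22 in both). Counting noise alone is argued against, since it is independent between groups, while permuting the DMSO gaps within 20 bins of expression gave at most 6 genes in both (10000 permutations, p = 0.0001, the smallest they can give). Of these genes 32.1% shared exon bases with another protein-coding gene on their strand, against 10.2% of the others (Fisher's exact test, odds ratio 4.176, interval 2.81 to 6.13, p = 1.01e-11), so division of reads between overlapping genes is a candidate source for part of them. The 71 without any overlap had a median 3' UTR of 3082 nt against 1462 nt, a difference of 1620 nt (permutation test, 100000 permutations, p = 1e-05, the smallest they can give). Read assignment that varies along 3' ends is a candidate source for these genes. The genes compared were not matched for transcript length, so the test cannot tell 3' UTR length from other traits of long transcripts. No biological explanation was tested, and 1 of the 131 genes was called.

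Several loci stand out by their counts, given in the order DMSO 1, DMSO 2, HJJ_3_5 1, HJJ_3_5 2. The readthrough gene MICOS10-NBL1 had 2304, 39, 2498 and 63, and NBL1, which it overlaps, 1417, 3520, 1457 and 2200. CLDN4, an epithelial claudin with no overlap in the annotation, had 13958, 714, 3085 and 1239. MYC had 549, 400, 691 and 166. TXNIP, a paralogue of ARRDC4, had 0 counts in all 4 libraries, while ARRDC4 averaged 400.3 CPM with DMSO; how reads were assigned is not known, so the 0 does not show that TXNIP was not expressed. ENSG00000263020 had 115, 15, 1237 and 1346, and shares exon bases with another gene. These loci were chosen after their values were seen.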
